A study of Mus musculus with 12 samples.

How the data were processed

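RNA was measured in mouse lens and in embryonic tissue on whole-genome Illumina bead arrays. Per the labels, all animals were wild-type ICR mice, an outbred strain, and biotin-labelled total RNA was hybridised, with 1 array per sample. The 12 arrays made 6 groups of 2: lens at postnatal days 8, 12, 20, 42 and 52 (written P8 to P52), and whole body, a pool of embryos at embryonic days 10, 11 and 12 without the eyes. The replicates of a group carried the letters A and B. The labels do not say how many animals went into a sample, their sex, or whether A and B came from different animals, so the spread between them may be smaller than that between animals. The series' design text also names embryonic lens stages and mutants, which were not used here.

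The authors exported the arrays from GenomeStudio, gene expression module 1.9.0 per the file headers. The deposited table used here holds an intensity for each of 45281 probes, the mean brightness of the beads of that probe, without background subtraction or normalization per the file headers. The same table gives a detection p-value for each probe, which per the file headers belongs to the same export and compares the probe with the negative control probes of its own array. It also gives the standard error over beads and the number of beads, and a block of 936 negative controls and 38 other controls. A shorter deposited table held the same intensity and p-value columns (largest difference 0). The authors also deposited background-subtracted, rank-invariant normalized intensity values on a linear scale, which equalled their value table (largest difference 0). These served only as an alternative. That table also held 12 arrays of another experiment, which were not used.

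Intensity values were background-corrected against the negative controls and quantile normalized between the 12 arrays with the neqc function of limma 3.58.1 in R 4.3.3, with an offset of 16, and put on the log2 scale. Background correction with an offset draws dim probes towards the floor and shortens their differences. Quantile normalization gives every array the same distribution of values, so it cannot show a change of the total amount of RNA, and it fixes the brightest ranks, where most lens crystallin probes lie. Probes were kept when their detection p was under 0.05 on at least 2 arrays, which left 22119. Each gene was represented by its probe with the highest mean, and 15108 genes were tested, 10300 with 1 detected probe and 4808 with several. Where other detected probes of a named gene went the opposite way, that is said beside it. Probes were named through the Entrez identifiers, accessions and symbols in the file with a table of current NCBI gene symbols. Only 8.86% of probes had a file position inside the gene's GRCm38 bounds, so no coordinates are given.

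Differences were tested with limma: a linear model with 1 mean for each of the 6 groups, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, two-sided. The comparisons were lens against whole body (the mean of the 5 stage means), each stage against whole body, P52 against P8, each consecutive step, any difference among the 5 stages (moderated F-test), and a slope on log2 of postnatal day over the 10 lens arrays. Errors given with log2 differences are the standard errors of this model, and errors of group values are SD over 2 arrays. The small number of arrays limits precision, and the 6 groups share an estimate of the spread. On simulated data with 200 changed genes in each of 5 runs, 68.1%, 98.2% and 100% of 1.5-fold, 2-fold and 4-fold changes were recovered for lens against whole body, with 8.6 false calls per run. For P52 against P8 these were 39.7%, 85.4% and 100%, with 9.2 false calls per run. The simulated noise was independent between genes and added after normalization, and far fewer genes were changed than were called in the data. These rates therefore need not hold for the data.

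The rule for named genes was fixed before the data were examined and left out clone names. For both main comparisons it took the 8 largest called differences in each direction among genes detected on at least 1 array of each group on both sides and with no overlap between arrays. It also took the 6 largest lower bounds in each direction for genes detected on no array of the dimmer side. For each stage against whole body and each step it took the 3 largest in each direction, across stages the 8 largest ranges, and for the age slope the 5 largest in each direction, both among genes detected on all 10 lens arrays. It also took all crystallins and the up to 4 members of each gene list with the largest differences. Any list member named beyond these was chosen after its values were seen. For these bounds, written as at least so many fold, the undetected side was set on each array to no less than the lowest normalized value of any detected probe. Some genes that the rule takes are not reported here.

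The 25 gene lists, also fixed before the data were examined, were crystallins, lens fibre membrane and cytoskeleton, lens epithelium, lens transcription factors, human cataract genes, basement membrane, cell cycle, cholesterol synthesis, glycolysis, oxidative phosphorylation, antioxidant genes, heat shock proteins, autophagy and lysosome, FGF signalling targets and Hox genes. Marker lists covered photoreceptors, pigmented epithelium with iris and ciliary body, cornea, erythroid cells, macrophages, blood vessels, fibroblasts, muscle, fetal liver and neurons. The 24 lists with at least 5 tested genes were tested with camera, a competitive set test, at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Another 4 lists, of immediate-early, X-escape, Y-linked and pancreatic acinar genes, were added after the data were seen.

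The deposited tables name no slides or scan dates, so a slide block could not be run. In the authors' table order the arrays fall into 2 sets of 6: P12, P52 and whole body come first, with median negative control intensities of 46.6 to 50.9, and P8, P20 and P42 follow, with 40.0 to 44.1. The sets were inferred from this. As each group lies in a single set, set could not be a term beside the group means, and comparisons within a set were computed instead. Alternatives covered background correction, normalization between arrays, detection filters, probes per gene, error models, thresholds, the arrays in the fit, a replicate block and the removal of each array. Lens arrays had 14111 to 15273 detected probes and whole body arrays 20268 and 20401.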

Results

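Gene expression was measured on 12 bead arrays: 2 of mouse lens at each of P8, P12, P20, P42 and P52, and 2 of whole embryo tissue without eyes. The series serves to extend a tool for finding genes of the lens and eye, and embryo tissue is its reference for expression outside the eye. Lens arrays were dimmer before normalization, with mean intensities of 145.6 to 187.7 against 331.4 and 340.1 in whole body. Of the probe intensity above the negative control median, crystallin probes gave 7.60% to 12.9% on lens arrays. On the whole body arrays they gave 0.00599% and 0.0233%. Replicates correlated across genes at r = 0.986 to 0.998, arrays of different lens stages at 0.953 to 0.987, and lens with whole body at 0.752 to 0.788. Genes are not independent replicates in these correlations. The first principal component of the 12 arrays held 77.1% of the variance and parted lens from whole body. Among the 10 lens arrays it held 52.8%, and the stages lay along it in order of age.

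In lens compared with whole body, all 16 crystallins and all 18 tested fibre cell genes were higher, and all 27 cell cycle genes, all 10 erythroid genes and 23 of 30 Hox genes were lower, with 2 Hox genes higher. The crystallin and erythroid list calls were lost at adjusted p = 0.0678 and adjusted p = 0.0531 with an estimated correlation. Crybb2, a beta-crystallin of the lens cytoplasm, was higher by 10.93 ± 0.09 log2 units (SE, n = 10 and 2 arrays, limma adjusted p = 3.06e-16). Hba-a1, an adult alpha-globin, was lower, at -8.24 ± 0.21, a size that is approximate since its whole body value of 15.46 on both arrays is the top value that normalization allows. The imprinted growth factor Igf2 was at -6.73 ± 0.22. Of 15108 genes tested, 10932 differed, 4934 higher and 5998 lower in lens, and 4451 of them differed at least 2-fold. All lens samples were postnatal and whole body was embryonic, so tissue and developmental age cannot be told apart in any of these differences.

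Other large differences in favour of lens were those of Crygc (10.47 ± 0.15), Crygs (10.28 ± 0.19), Cryaa (10.07 ± 0.13), Lim2 (10.02 ± 0.07), Crybb1 (9.99 ± 0.19), Crybb3 (9.96 ± 0.16) and Mip (9.87 ± 0.15). Lim2 is a fibre cell membrane protein and Mip the lens water channel. The whole body side of Crybb2, Crygc, Cryaa and Lim2 was detected on 1 of 2 arrays, and crystallins lie in the brightest ranks, which quantile normalization fixes, so the sizes are approximate and their order is not measured. Some lens genes were detected on neither whole body array. Grifin, a lens galectin, was at least 870-fold higher in lens, and Bfsp2, of the beaded filament of fibre cells, at least 734-fold. Lgsn was at least 404-fold higher, Birc7 at least 365-fold, Lctl at least 110-fold, and Hsf4, a heat shock transcription factor needed in the lens, at least 108-fold.

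All 16 crystallins rose (16 adjusted over the list alone, camera adjusted p = 7.39e-13, and adjusted p = 0.0678 with an estimated correlation). The whole body arrays differed widely for Cryba4 (9.56 above whole body), Cryba2 (9.41), Crygd (9.16), Crygb (8.56) and Cryba1 (8.17), with whole body SDs of 0.98, 1.15, 1.15, 1.31 and 1.38. Without whole body A these 5 were at 8.86, 8.60, 8.35, 7.64 and 7.19, and without whole body B at 10.25, 10.22, 9.97, 9.48 and 9.15. Cryga was at 9.53 and Crygn at 9.43, each detected on 1 of 2 whole body arrays, and Cryab at 7.90. Crygf and Cryge, undetected in whole body, were at least 67.8-fold and 66.2-fold higher. All 18 tested fibre membrane and cytoskeleton genes rose (18 adjusted over the list alone, adjusted p = 4.98e-14), and this call held at adjusted p = 0.00681 with an estimated correlation. They included Tdrd7 (7.22 ± 0.07), a granule protein that is mutated in cataract, and Dnase2b (at least 61.3-fold), the nuclease that removes fibre cell DNA.

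**Figure D1:**
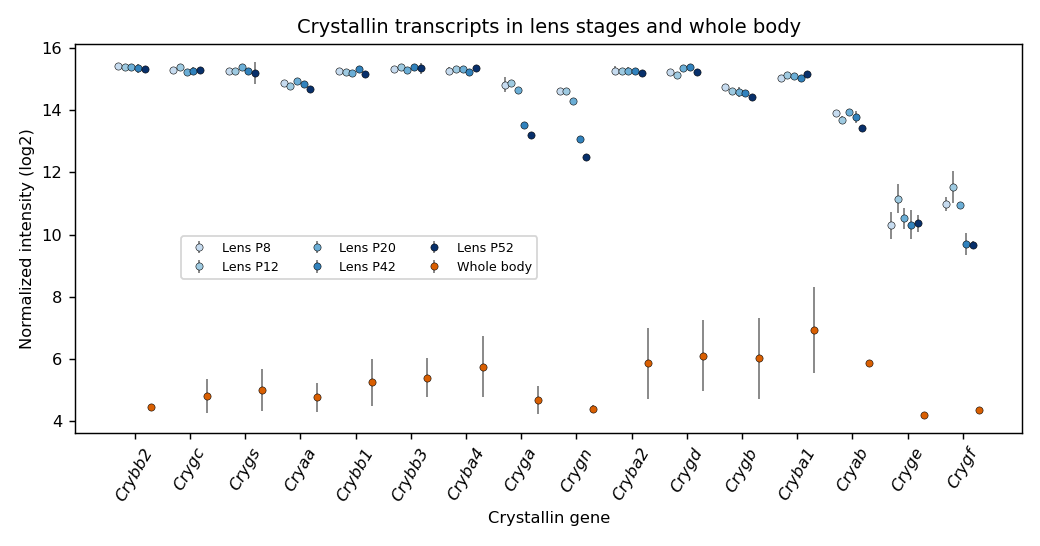
Normalized intensity (log2, vertical axis) of the 16 crystallin genes (horizontal axis), as means of 2 arrays with SD bars, for the lens stages in blue shades from P8 to P52 and for whole body in orange. Every lens mean lies above the whole body mean of its gene, and Crygn fell from 14.62 at P8 to 12.49 at P52.

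Of 8 lens epithelium genes, 6 rose and 2 fell (8 adjusted over the list alone, adjusted p = 0.0221, and adjusted p = 0.151 with an estimated correlation). Aqp1, a water channel, rose by 4.23 ± 0.08, and the gap junction gene Gja1 was at -1.10 ± 0.12. Of 15 lens transcription factors, 9 rose and 3 fell (13 adjusted over the list alone, adjusted p = 0.00760, and adjusted p = 0.0531 with an estimated correlation). Prox1 rose by 5.41 ± 0.09 and Pitx3, detected on 1 of 2 whole body arrays, by 3.89 ± 0.13, and Meis1 was at -2.08 ± 0.15. Of 21 human cataract genes other than crystallins, 16 rose and 5 fell (21 adjusted over the list alone, adjusted p = 3.11e-05, and adjusted p = 0.0531 with an estimated correlation). Of 18 basement membrane genes, 11 rose and 4 fell (15 adjusted over the list alone, adjusted p = 0.00760, and adjusted p = 0.0678 with an estimated correlation). The collagen IV chains Col4a3 (at least 20.9-fold) and Col4a4 (at least 14.7-fold), of the lens capsule, rose, and fibronectin, Fn1, was at least 11.7-fold lower. Of 19 autophagy and lysosome genes, 13 rose and 3 fell (16 adjusted over the list alone, adjusted p = 4.95e-04, and 0.0291 with an estimated correlation). Gabarapl1 rose by 3.90 ± 0.06 and Ctsl, a lysosomal protease, by 2.84 ± 0.10. With 75th percentile scaling the calls of the epithelium (adjusted p = 0.182), transcription factor (0.199), basement membrane (0.199) and autophagy and lysosome (0.0835) lists were lost, and the first 3 of these also with that percentile over probes detected on all arrays (0.122, 0.149 and 0.149). The epithelium call was lost with cyclic loess too (0.0535), and the basement membrane call with the authors' values (0.0566).

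On the other side, the imprinted RNA H19 was at -7.22 ± 0.15 in lens relative to whole body. Hbb-b1, a beta-globin, was at -6.08 ± 0.07, Igdcc3 at -5.56 ± 0.19, Fxyd6 at -5.17 ± 0.12, and both Zfp36l1 and the histone gene H2ac24 at -5.12, where whole body H2ac24 is in the brightest ranks too. Genes detected on no lens array included the embryonic globin Hba-x, at least 631-fold lower, and Sox11, a factor of neural progenitors, at least 167-fold lower. The chemokine gene Cxcl12 was at least 58.3-fold lower, Ebf3 at least 55.0-fold, and Nppa, the atrial natriuretic peptide gene, at least 34.6-fold.

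All 27 cell cycle genes fell (27 adjusted over the list alone, adjusted p = 1.42e-11, and 0.00589 with an estimated correlation). Mcm5, of the replicative helicase, was at -5.09 ± 0.08 and Mki67, a proliferation marker, at -4.11 ± 0.15. Of 30 Hox genes, 23 fell and 2 rose (25 adjusted over the list alone, adjusted p = 4.33e-06, and 0.0140 with an estimated correlation), with Hoxc6 at least 22.7-fold lower. Markers of tissues that the embryo holds and the lens lacks were also lower. All 10 erythroid genes fell (10 adjusted over the list alone, adjusted p = 2.69e-06, and adjusted p = 0.0531 with an estimated correlation). All 10 neuronal genes fell (10 adjusted over the list alone, adjusted p = 1.14e-05, and 0.0174 with an estimated correlation), as did 14 of 15 muscle genes (14 adjusted over the list alone, adjusted p = 4.33e-06, and 0.0191 with an estimated correlation). Of 12 fibroblast genes, 9 fell (9 adjusted over the list alone, adjusted p = 0.00171, and 0.0440 with an estimated correlation). Of 12 vessel genes, 10 fell and 1 rose (11 adjusted over the list alone, adjusted p = 0.00121, and adjusted p = 0.0532 with an estimated correlation). Of 9 fetal liver genes, 7 fell and 1 rose (8 adjusted over the list alone, adjusted p = 0.0294, and adjusted p = 0.115 with an estimated correlation). This last call was also lost with 75th percentile scaling in both forms (adjusted p = 0.128 and 0.0946), with cyclic loess (0.0535) and without scaling (0.230).

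The remaining lists went both ways and did not pass the list test, with adjusted p from 0.0635 to 0.803. Some passed under alternatives. With the authors' values glycolysis (median 1.17, adjusted p = 9.95e-04), oxidative phosphorylation (1.15, 1.71e-05) and antioxidant genes (0.94, 0.0106) were called up. Antioxidant genes were also called up without crystallin probes (0.0490), without a detection filter (0.0368), without whole body B (0.0499) and, relative to all genes, without scaling (0.0153, median -0.89). Among 23 antioxidant genes, 14 rose and 7 fell (22 adjusted over the list alone), with Hmox1, the haem oxygenase, higher by 6.15 ± 0.13 and the metallothionein Mt1 at -3.01 ± 0.12. Among 15 glycolysis genes, 5 rose and 6 fell (11 adjusted over the list alone), and Aldoc, an aldolase, was higher by 7.54 ± 0.10. Oxidative phosphorylation had 16 genes up and 10 down of 34 (26 adjusted over the list alone), and cholesterol synthesis 7 up and 8 down of 17 (15 adjusted over the list alone). Heat shock proteins had 3 up and 3 down of 14 (6 adjusted over the list alone), with Hspb1, a small heat shock protein, higher by 5.85 ± 0.09. FGF signalling targets had 4 up and 5 down of 11 (9 adjusted over the list alone). The macrophage list had 2 up and 6 down of 9 (8 adjusted over the list alone), and the cornea list 3 up and 6 down of 9 (9 adjusted over the list alone). The pigmented tissue list had 4 up and 2 down of 8 (6 adjusted over the list alone), and its median of 0.20 and mean of -0.16 differed in sign, as did the median of -0.0014 and mean of 0.60 for glycolysis. Only 3 of 17 photoreceptor genes could be tested, too few for the list test. They were called higher (3 adjusted over the list alone), Cnga1 by 1.01, Rom1 by 0.41 and Pde6a at least 1.17-fold, but without scaling between arrays they were lower, at -0.14, -0.37 and -0.19. Rom1 was not called without whole body A (0.44) or B (0.39), nor Pde6a without either of these (0.29 and 0.33), P8 A (0.29), P20 A (0.29), P42 B (0.29) or P52 B (0.29). Rom1 was also not called with the authors' values (0.26) or without a detection filter (0.41), nor Pde6a without background correction (0.16) or a filter (0.31).

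The choice of scaling moved the median lens difference over all genes from -0.05 to 0.35 with 75th percentile scaling, to 0.47 when that percentile was taken over probes detected on all arrays, and to -1.47 without scaling, where the medians of the epithelium (-0.13), transcription factor (-0.29), basement membrane (-0.22) and autophagy and lysosome (-0.65) lists lay below 0 but above that shift. With P12 and P52 alone as lens, in the same array set as whole body, 10552 genes differed.

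**Figure D2:**
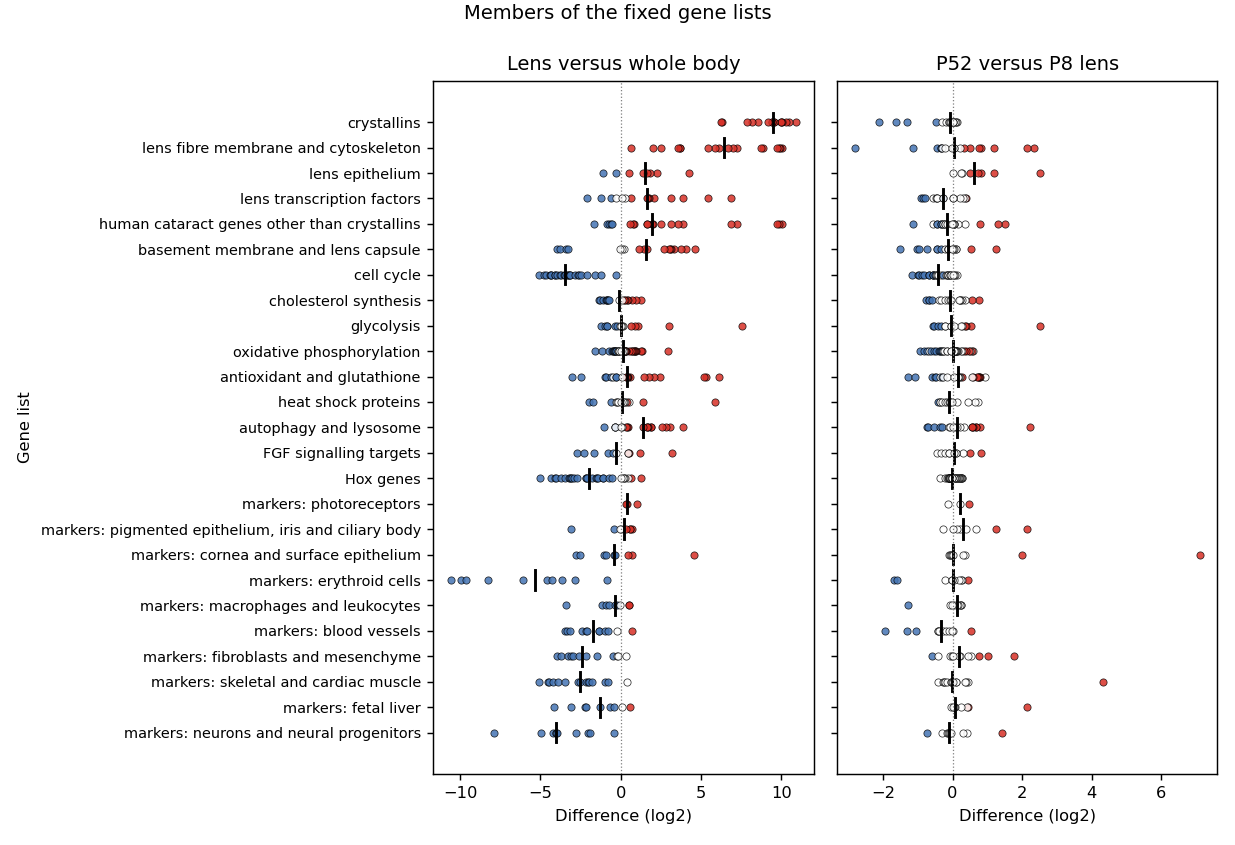
Log2 differences (horizontal axes) of the tested members of each gene list (vertical axis) for lens against whole body on the left and P52 against P8 lens on the right. Red points were called higher, blue points lower, white points were not called, and the black bar is the list's median. The crystallin median was 9.48 on the left and -0.09 on the right.

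Each stage was also set against whole body. Crybb2, Crygc and Crygs rose at every stage, with the same limits on their sizes as for all stages together. Hba-a1 was among the largest falls at every stage, but its whole body value is at the top of the scale, so no sizes are given by stage. The cartilage and progenitor factor Sox9 was at -6.29 ± 0.30 and the noncoding RNA Miat at -5.48 ± 0.19 at P8, each detected on 1 of 2 arrays of that stage, so these sizes are approximate, as are all others with such detection. The embryonic globins Hbb-y and Hbb-bh1 were among the largest falls at P12 and P42, where each was detected on 1 of 2 arrays. Hbb-bh1 was at -9.40 ± 0.27 and -9.37. No sizes are given for Hbb-y, whose lens arrays differed widely (SD 1.24 and 1.07). Dlk1, an imprinted gene detected on 1 of 2 P20 arrays, was at -7.94 ± 0.19 and H19 at -7.85 ± 0.19 at P20, and at P52 H19, detected on 1 of 2 arrays, was at -8.86 and Igf2 at -8.86 ± 0.29. The genes called numbered 9622 at P8 (4258 higher), 9765 at P12 (4255 higher), 10144 at P20 (4481 higher), 10041 at P42 (4445 higher) and 9859 at P52 (4351 higher). At all 5 stages 2907 genes were higher and 4220 lower. Stages with independent calls would share 30.1 and 99.0 genes, and since the same whole body arrays serve every stage, sharing above this is built in. In 20 simulations without any effect, at most 0 genes were shared. These hold no effect to share, so they do not measure the sharing that the common whole body arrays build in.

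P52 against P8 asks how lens expression changed with age. Of the lens epithelium genes 5 of 8 rose between them, and of the cell cycle genes 12 of 27 fell, and both list calls were lost with an estimated correlation (adjusted p = 0.307 and adjusted p = 0.179). Aldh3a1, an aldehyde dehydrogenase that is abundant in the cornea, rose by 7.13 ± 0.20 log2 units (SE, n = 2 and 2 arrays, limma adjusted p = 4.46e-10), or 140-fold. Igf2 fell by 5.20 ± 0.29, or 36.8-fold, and H19, its neighbour in the imprinted cluster, by 3.99 ± 0.19, an approximate size since it was detected on 1 of 2 P52 arrays. Of 15108 genes, 4518 differed, 2214 higher and 2304 lower at P52, and 973 differed at least 2-fold.

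Other large rises were those of the carboxylesterase Ces5a (4.43 ± 0.09), the myosin light chain Myl4 (4.33 ± 0.12), the phospholipid transporter Abcb4 (4.18 ± 0.14), Dapl1 (4.15 ± 0.15), the granule membrane glycoprotein Gp2 (4.12 ± 0.11), Ankrd24 (3.88 ± 0.23) and the protease inhibitor Serpina3n (3.61 ± 0.18). Genes detected on neither P8 array included the amylase gene Amy2a5, at least 15.4-fold higher at P52, Gdf10 (at least 8.40-fold), Mia (at least 7.81-fold), Hhatl (at least 6.49-fold) and Scd1, a fatty acid desaturase (at least 6.05-fold). The falls included the gastrin and cholecystokinin receptor gene Cckbr (-4.43 ± 0.29), the endothelin receptor gene Ednrb (-4.00 ± 0.15), Slc46a3 (-3.98 ± 0.09), Igf2bp3, which encodes a binding protein of Igf2 mRNA (-3.79 ± 0.17), Gask1b (-3.76 ± 0.16) and the actin crosslinker gene Actn2 (-3.73 ± 0.09). Cckbr, Igf2bp3 and Gask1b were each detected on 1 of 2 P52 arrays, so their sizes are approximate, and Cckbr was at -3.82 without P52 A and -5.05 without P52 B. Capn3, a calpain protease, was detected on neither P52 array and was at least 20.1-fold lower. Pla2g7 was at least 7.69-fold lower, the amino acid transporter gene Slc38a5 at least 6.89-fold, Ccdc3 at least 5.84-fold, Akap14 at least 5.57-fold and Timeless at least 5.30-fold (1 of 2 probes opposite).

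**Figure D3:**
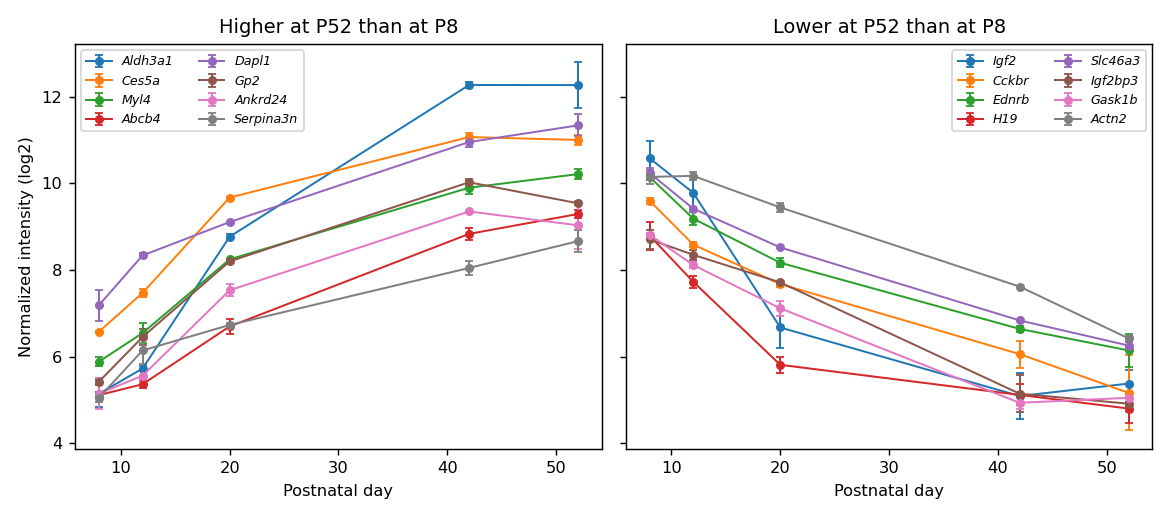
Normalized intensity (log2, vertical axes) against postnatal day (horizontal axes) for genes that rose most (left) and fell most (right) from P8 to P52, as means of 2 arrays with SD bars. Aldh3a1 went from 5.14 to 12.27 and Igf2 from 10.57 to 5.38.

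Of 8 lens epithelium genes, 5 rose and none fell (5 adjusted over the list alone, camera adjusted p = 0.00364, and adjusted p = 0.307 with an estimated correlation). They included Aqp1 (2.50 ± 0.10), the laminin receptor gene Itga6 (1.19 ± 0.23) and the growth factor receptor genes Fgfr2 (0.83 ± 0.07) and Pdgfra (0.49 ± 0.12). Gja1 also rose (0.73 ± 0.16), but was not called without P8 A (0.55). The other 3 genes, Cdh1, Foxe3 and Fzd6, were not called. Of 27 cell cycle genes, 12 fell and none rose (14 adjusted over the list alone, adjusted p = 0.00367, and adjusted p = 0.179 with an estimated correlation). Mcm5 was at -1.16 ± 0.10, Cdk1, the kinase of mitosis, at -0.98 ± 0.21 (detected on 1 of 2 P52 arrays), and the centromere histone gene Cenpa at -0.97 ± 0.12. The median of the list was -0.40, or -0.28 with undetected genes at their bound.

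No other list passed the test, with adjusted p from 0.155 to 0.961. Under alternatives the crystallin list was called down with cyclic loess (median -0.43, adjusted p = 0.0187) and without a detection filter (0.0276), the vessel list down without P52 B (0.0347) and without a filter (0.0257), and the cornea list up without a filter (0.0276). Of 16 crystallins, 4 fell (4 adjusted over the list alone): the gamma-crystallins Crygn (-2.13 ± 0.09), Cryga (-1.62 ± 0.17) and Crygf (-1.32 ± 0.21), and Cryab (-0.47 ± 0.11), which was not called with the authors' values (-0.19, adjusted p = 0.481), with 75th percentile scaling in either form (-0.23 and -0.24), without scaling (-0.23), without P8 A (-0.41) or without P52 B (-0.40). The other 12 were not called. Crygb was at -0.31, Cryaa at -0.18, Crybb1 and Crybb2 at -0.10, Cryba2 at -0.07, Crygs at -0.04, Cryge at 0.06 and Crygc at 0, as quantile normalization fixes the brightest ranks. Cryba1 (0.12), Cryba4 (0.09), Crybb3 (0.01) and Crygd (0.00043) changed sign with cyclic loess, to -0.22, -0.31, -0.37 and -0.36. Calls arose for Crybb3 with the mean of its probes (-0.65, adjusted p = 0.00709) and for Crybb2 with cyclic loess (-0.52, adjusted p = 0.0409). For Crybb3, and for Cryba1 with a mean over probes of -0.030, another detected probe therefore went the opposite way from the chosen probe. Of 18 fibre genes, 7 rose and 5 fell (12 adjusted over the list alone). The water channel gene Aqp5 rose by 2.36 ± 0.10 and Lgsn by 2.16 ± 0.09, and Caprin2, an RNA-binding protein gene, was at -2.82 ± 0.19. Of 15 transcription factors, 1 rose and 4 fell (5 adjusted over the list alone), with Mafg at -0.90 ± 0.11 and Prox1 at -0.85 ± 0.12. Of 21 cataract genes, 3 rose and 5 fell (8 adjusted over the list alone), and of 18 basement membrane genes, 2 rose and 6 fell (8 adjusted over the list alone), with Col18a1 at -1.52 ± 0.27 and Lamb2 at 1.26 ± 0.20.

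Metabolic lists went both ways. Of 15 glycolysis genes, 4 rose and 4 fell (9 adjusted over the list alone), with the phosphofructokinase gene Pfkp at 2.52 ± 0.14. Of 34 oxidative phosphorylation genes, 4 rose and 10 fell (14 adjusted over the list alone), with Ndufs3 at -0.94 ± 0.10. Of 23 antioxidant genes, 7 rose and 6 fell (16 adjusted over the list alone). Gpx1, a glutathione peroxidase, was at -1.28 ± 0.09 and catalase, Cat, at 0.77 ± 0.12. Of 19 autophagy and lysosome genes, 7 rose and 5 fell (14 adjusted over the list alone), with Ctsl at 2.22 ± 0.13. Cholesterol synthesis had 2 up and 4 down of 17 (6 adjusted over the list alone), heat shock proteins 1 down of 14 (1 adjusted over the list alone), FGF signalling targets 2 up of 11 (2 adjusted over the list alone) and Hox genes 0 of 30 in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05). Of the 30 Hox genes, 26 were detected on no array of the dimmer side, so the floor limits what this count can show. The FGF target Il17rd was not called with the authors' values (0.044, adjusted p = 0.893) or the mean of its probes (0.18). Its call was also lost without P8 A (0.53), P8 B (0.49), P52 A (0.53) or P52 B (0.49).

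Among markers of other tissues, Aldh3a1 and the keratin gene Krt13 (at least 2.65-fold) rose of 9 cornea genes (2 adjusted over the list alone), and the other 7, Krt5 (-0.04) and Krt14 (0.30) among them, were not called. Of 8 genes of pigmented tissue, 2 rose (2 adjusted over the list alone), Ttr at least 3.10-fold and Dct at least 1.59-fold, and neither was called with the authors' normalized values. The P52 arrays differed widely for Ttr, whose fitted difference was 1.16 without P52 A and 3.13 without P52 B. Of 10 erythroid genes, Hbb-b1 (-1.70 ± 0.09, 1 of 10 probes opposite) and Hba-a1 (-1.60 ± 0.28) fell and Slc4a1 rose (3 adjusted over the list alone). Of 12 vessel genes, 3 fell, Cldn5 at least 2.61-fold, Esam at least 1.81-fold and Tek at -1.06 ± 0.18, and Kdr rose (4 adjusted over the list alone). Of 12 fibroblast genes, 3 rose and 1 fell (4 adjusted over the list alone), with Col6a1 at least 2.32-fold higher. The fall, of Col5a1, was not called without P8 A (-0.50) or P52 B (-0.44) or with the authors' values (-0.73, adjusted p = 0.0526). Pdgfrb was not called without P8 B (0.59) or P52 A (0.74), nor Col6a2 without P8 A (0.96). Of 9 macrophage genes, only Laptm5 was called, at least 1.65-fold lower (1 adjusted over the list alone). Of 15 muscle genes, only Myl4 was called (1 adjusted over the list alone). Of 10 neuronal genes, 1 rose and Map2 (-0.74 ± 0.16, 2 of 4 probes opposite, and not called at -0.20 with the mean of its probes) fell (2 adjusted over the list alone). Of 9 fetal liver genes, 2 rose (2 adjusted over the list alone), and of 3 photoreceptor genes, Rom1 (1 adjusted over the list alone). The fetal liver gene Ahsg was not called without P8 A (0.46), P8 B (0.45), P52 A (0.47) or P52 B (0.44). Its call was also lost with 75th percentile scaling (0.27) and cyclic loess (0.23), among other settings. The rises of Slc4a1 (0.44), Kdr (0.54) and Rom1 (0.46) and the fall of the heat shock gene Hspd1 (-0.43) were not called without P8 A (0.51, 0.46, 0.34 and -0.36). Other single arrays also ended calls, to 0.26 for Slc4a1 and 0.36 for Kdr without P52 A and 0.35 for Rom1 without P52 B, which was detected on 1 of 2 P8 arrays. Without P8 B Slc4a1 (0.38) and Kdr (0.63) were not called, without either whole body array none of the 3, and without either P12 array Rom1 was not. The 3 were also not called with only the compared groups in the fit (adjusted p = 0.124, 0.142 and 0.170), without a detection filter, with array weights or with lens arrays normalized alone, and each was lost in further settings. Hspd1 was not called without scaling (-0.49). Median and mean had opposite signs for glycolysis (-0.05 and 0.13), oxidative phosphorylation (0.0019 and -0.09), Hox genes (-0.03 and 0.02), erythroid cells (0.03 and -0.23), macrophages (0.13 and -0.04, with the test direction up), muscle (-0.03 and 0.29) and neurons (-0.09 and 0.06). Many marker genes were detected on no array of the dimmer side. These were 12 of 15 muscle, 9 of 12 vessel, 8 of 12 fibroblast and 8 of 10 neuronal genes. Among the others were 7 of 10 erythroid, 7 of 9 macrophage, 7 of 9 fetal liver and 6 of 9 cornea genes. With undetected genes at their bound, the medians of these lists and of the Hox genes were 0.

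P8 and P52 lie in different array sets, so age was also compared within each set. P42 against P8 gave 3606 genes and P52 against P12 3621, of which 2352 were called in the same direction in both and 23 in opposite directions (432.1 expected of independent lists for the same direction). The Y-linked gene Ddx3y was higher at P42 (8.55) than at P8 (5.22) but lower at P52 (4.92) than at P12 (7.39). Within either pair alone, age can therefore not be told apart from the sex of the animals, which the labels do not give. Aldh3a1 rose by 7.13 and 6.54 in these comparisons, Igf2 was at -5.49 (detected on 1 of 2 P42 arrays) and -4.41, Aqp1 at 2.08 and 2.44 and Mcm5 at -0.98 and -1.07. The epithelium list was called up (adjusted p = 0.0106 and 0.00321) and the cell cycle list down (0.00318 and 0.00321) in both, at the preset correlation alone. The vessel marker list was also called down from P12 to P52 (adjusted p = 0.00321, median -0.41), where 5 of its 12 genes fell, and lay at 0.0741 from P8 to P42, where 3 fell. For P52 against P8 the epithelium and cell cycle calls were lost at adjusted p = 0.307 and adjusted p = 0.179 with an estimated correlation. The vessel list was not called there (camera adjusted p = 0.155), and 9 of its 12 genes were detected on no array of the dimmer side.

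Between consecutive stages fewer genes differed than between P8 and P52. From P8 to P12, 281 genes differed (180 higher). The zinc finger gene Sall3 rose by 2.80 ± 0.22 (1 of 2 probes opposite), the Y-linked helicase gene Ddx3y by 2.17 ± 0.23 and the chemokine receptor gene Ackr4 by 1.68 ± 0.17. The synapsin gene Syn2 (-1.34 ± 0.19), Timeless (-1.17 ± 0.19) and Gpr19 (-1.08 ± 0.21) fell, but were not called without P8 A (-1.29, -1.09 and -1.15) or P8 B (-1.39, -1.25 and -1.02). Gpr19 was also not called without P12 A (-1.16), P12 B (-1.01) or either whole body array, Timeless without P12 A (-1.03) and Syn2 without P12 B (-1.10). Gpr19 was not called with the authors' values (-1.25), nor Timeless with the mean of its probes (-0.62) or with only the compared groups in the fit (adjusted p = 0.0526). From P12 to P20, 856 genes differed (470 higher), with rises of Aldh3a1 (3.04 ± 0.20), Chac1 (2.45 ± 0.36), which degrades glutathione, and Ces5a (2.20 ± 0.09). Igf2 (-3.11 ± 0.29), the ceramidase gene Acer2 (-2.46 ± 0.23) and Ddx3y (-2.39 ± 0.23, detected on 1 of 2 P20 arrays) fell. From P20 to P42, 1388 genes differed (722 higher). The immediate-early factor Egr1 rose by 3.78 ± 0.20, Ddx3y by 3.55 ± 0.23 and Aldh3a1 by 3.50 ± 0.20, and Hbb-b1 (-3.07 ± 0.09), Hba-a1 (-2.90 ± 0.28, detected on 1 of 2 P42 arrays) and the actin bundler gene Fscn1 (-2.59 ± 0.17) fell. From P42 to P52, 92 genes differed (42 higher). Igfl3 rose by 1.75 ± 0.21, Hbb-b1 by 1.39 ± 0.09 (1 of 10 probes opposite) and Sox9 by 1.58 ± 0.30, whose call was lost without P42 A (adjusted p = 0.216), P42 B (0.122), P52 A (0.152) or any single P12 or whole body array, with the authors' values (0.0536), the mean of its probes (0.107), no intensity trend (0.0695), array weights (0.0568), only the compared groups (0.180) or a replicate block (0.0644). Igfl3 and Hbb-b1 were not called with only the groups compared in the fit (adjusted p = 0.0980 and 0.185). In the same step Fos (-4.24 ± 0.24), Ddx3y (-3.62 ± 0.23) and Egr1 (-3.18 ± 0.20) fell, with Fos and Ddx3y detected on 1 of 2 P52 arrays.

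Several of these genes marked single stages. Ddx3y was at 8.55 ± 0.16 at P42 (SD, n = 2) and 7.39 ± 0.02 at P12, against 5.22, 4.99 and 4.92 at P8, P20 and P52 and 8.72 in whole body. Xist, the X-inactivation RNA made in female cells and chosen after its values were seen, was at 4.24 at P42 and at 8.34 to 9.05 at the other stages. P8 and P52 were thus alike in low Ddx3y and high Xist. Fos stood at 9.44 ± 0.39 at P42 and at 4.53 to 5.20 at the other stages. Hbb-b1 went from 8.28 at P8 to 9.66 at P12, 8.26 at P20, 5.19 at P42 and 6.58 at P52. Without P42, 10855 genes differed between lens and whole body and 4543 across stages, and without P12, 10975 and 4389.

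**Figure D4:**
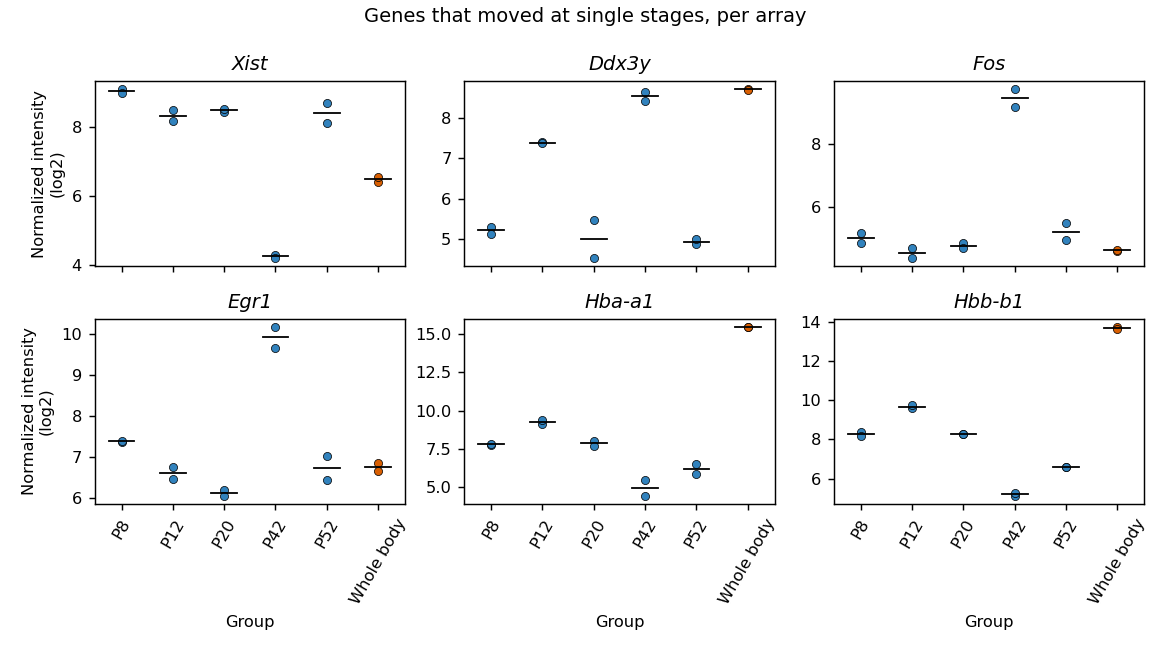
Normalized intensity (log2, vertical axes) of 6 genes on each array (points) by group (horizontal axes), with bars at group means, lens in blue and whole body in orange. At P42 Xist was lowest and Fos and Egr1 were highest, and Hbb-b1 was lowest there.

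Counts for the steps moved when a single array was left out, also where that array had no part in the step. The count from P8 to P12 was 108 without P8 A, 52 without P8 B, 131 without P12 A, 78 without P12 B, 116 without whole body A and 117 without whole body B. From P12 to P20 it was 360 without P12 A, 440 without P12 B, 280 without P20 A, 494 without P20 B, and 525 and 522 without whole body A and B. From P20 to P42 it was 734 without P20 A, 848 without P20 B and 753 without P42 B. From P42 to P52 it was 27 without P42 A, 30 without P42 B, 253 without P52 B, and 48 without either whole body array. All steps but that from P20 to P42 cross the array sets, so within a single such step set and age cannot be told apart. The step from P20 to P42 holds the changes of Ddx3y, Xist, Fos and Egr1 at P42, so it is no clean measure of age either.

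Across the 5 lens stages, 4699 genes differed. Among genes detected on all 10 lens arrays, the largest ranges of stage means belonged to Aldh3a1 (7.13, lowest at P8, highest at P42), Gp2 (4.60), Ces5a (4.49), Hbb-b1 (4.47, highest at P12, lowest at P42), Myl4 (4.33), Ankrd24 (4.21), Abcb4 (4.18) and Dapl1 (4.15). A slope on age was called for 4024 genes, 1952 upward and 2072 downward. Per doubling of age Aldh3a1 rose by 2.94 ± 0.14 log2 units, Ces5a by 1.74 ± 0.11, Myl4 by 1.68 ± 0.06, Gp2 by 1.67 ± 0.11 and Abcb4 by 1.66 ± 0.08. Ednrb and Slc46a3 were both at -1.46, Mfap4, a microfibril-associated protein gene, at -1.42 ± 0.10, and Rnf113a1 (± 0.06) and Actn2 (± 0.13) at -1.38. With array set as a covariate 4120 genes had a slope, 3860 of them shared with the same direction, and the set term was called for 6 genes.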

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

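All tests of explanations in this part were chosen after the patterns were seen, and only for the X-linked genes that escape inactivation was the bound set before their own values were.

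Effects against whole body differed between stages in direction for 233 genes, each higher than whole body at some stage, lower at another, and different across stages by the limma F-test. Of these genes, 4 with the largest ranges of stage means were Xist (4.81), Ednrb (4), Gask1b (3.88) and Egr1 (3.78). Ednrb went from 0.59 ± 0.15 (SE) above whole body at P8 to -3.41 ± 0.15 at P52. Gask1b went from 1.97 ± 0.16 at P8 to -1.80 ± 0.16 at P52, where it was detected on 1 of 2 arrays. Egr1 was 3.15 ± 0.20 above whole body at P42.

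Xist was above whole body at P8, P12, P20 and P52 (1.86 to 2.57) and at -2.24 ± 0.17 at P42, where all 4 of its probes lay between 4.23 and 4.49, and Ddx3y was highest there among lens stages. A difference between the array sets is argued against, since Xist at P42 lay 4.25 below the lower of P8 and P20, which share its set. The sex of the animals may account for it: Kdm6a, Kdm5c, Ddx3x and Eif2s3x, X-linked genes that escape inactivation, had a median of -0.53 at P42 relative to P8, P20 and P52 (from -0.72 to -0.13), as an all-male P42 group would give. Of these 4 genes, Kdm5c lay near the floor, detected on no P42 or P52 array and on 1 of 2 arrays at P8 and at P20. A mislabelled sample was not tested, and Ddx3y at P12 held 39.4% of its P42 excess. X-linked genes were called from P20 to P42 in 12.2% of cases and autosomal genes in 9.72% (Fisher's exact test, p = 0.121, two-sided).

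Immediate-early genes, which respond within minutes to stress or growth signals, were high at P42: 8 of 17 tested rose from P20, Klf4 among them though detected on no lens array, and none fell (camera p = 3.20e-11, and p = 3.76e-04 with an estimated correlation), and 7 fell and 1 rose to P52 (p = 8.74e-14, and 1.98e-04). This list was added after the data were seen and holds Egr1 and Fos, which stood out in these steps. Its p-values, which were not adjusted, therefore partly restate that pattern. The array sets are argued against, since these 8 exceeded P8, which shares the set of P42, by a median of 1.08. P8 had no part in choosing the 8, but P42 had, which may draw this median upward. A lasting change with age is also argued against, since P52 minus P20 had a median of -0.19. Male RNA stays open: the P12 values of the 8 lay below those expected from the male share by a median of 0.46, inside the bound of 0.5 set for it, though all 8 lay below (by 0.14 to 3.66), and that share rests on Ddx3y alone. For 4 of the 8 the expected P12 excess was itself 0.5 or less, so this median could hardly pass the bound and cannot decide. The other 4, Fos, Egr1, Junb and Fosb, lay below by 3.66, 2.19, 1.98 and 0.59, a split chosen after the values were seen. Handling of the tissue could also be the source: 0 of the 8 were as high at another stage, and with P42 a single group it cannot be told apart from a state of that age, which was not tested.

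Before scaling, the median gene was at -1.47 on lens arrays relative to whole body. Weaker hybridisation or scanning is argued against, as the spiked hybridisation controls were brighter on lens arrays by 0.24. Fewer expressed genes alone would leave shared genes level, but 7977 genes detected on all arrays had a median of -1.78. Crystallin transcripts taking up the labelled RNA may contribute. Their largest share of intensity above the negative control median would lower other genes by only -0.20. However, 12 to 15 of the 20 brightest probes on lens arrays were crystallin probes, whose signal need not follow their amount, so this stays open. The spiked controls do not measure the amount of labelled sample RNA, which was not tested. A lower RNA content of lens cells, a biological difference, was not tested either.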

How the results depend on the processing

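The no-scaling, second 75th percentile, array-set and left-out-stage alternatives were chosen after seeing the data. A slide block could not be run, and list tests have no robust variant. Letters A and B did not pair the samples: the 15 correlations of A minus B between groups ran from -0.17 to 0.17. Signal over background limits dim genes: lens arrays detected at most 33.7% of probes. Among named genes 4619 of 4744 values under other settings and 3416 of 3492 without single arrays kept direction and side of the threshold. List medians changed sign in 65 cases, 4 of them for called lists, all without scaling for lens against whole body, where the test direction, relative to all genes, turned for 0 called lists.

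Counts changed by more than 1.5 times as follows; where no cause is given, the cause was not tested. A 2-fold minimum, which removes small changes by construction, gave 4451 genes for lens against whole body (4306, 4453, 4763, 4813 and 4758 by stage), 973 for P52 against P8, 37, 129, 237 and 32 for the steps in order, 1300 across stages and 71 slopes. An adjusted p under 0.01 gave 2856 for P52 against P8, 55, 282, 636 and 24 for the steps, 2832 across stages and 2654 slopes. With only the compared groups in the fit, which leaves fewer arrays to estimate the spread, the steps gave 38, 490, 855 and 8. P8 to P12 gave 149 with 75th percentile scaling, 183 without a detection filter, 144 without the intensity trend, 185 with a replicate block and 167 with lens arrays normalized alone. P42 to P52 gave 162 with the authors' values in either table, 162 with every probe tested and 40 with array weights. Without scaling the first 3 steps gave 60, 1839 and 860. For lens against whole body, 15 lists became 7 with an estimated correlation, 23 with directional fry and 24 with mixed fry. For P52 against P8, 2 lists became 0, 14 and 23, and 5 without a detection filter. Fry tests lists without comparing them with other genes.

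Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 8969 to 11060 genes for lens against whole body, and by stage 7948 to 9800, 8096 to 9961, 8484 to 10282, 8500 to 10272 and 8332 to 9935. P52 against P8 gave 3370 to 4560, the steps 52 to 362, 280 to 998, 734 to 1538 and 27 to 253, all stages 3872 to 4562, slopes 3472 to 4136, and lists 15 to 16 and 2 to 3. The lowest step counts came without P8 B, P20 A, P20 A and P42 A, and the highest of the last step without P52 B.

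Reversals against whole body were Lyz2 at 0.031 and 0.15 with both forms of 75th percentile scaling and 0.12 without a filter, and Ldha at 0.26 with the authors' values. Without scaling these were Dhcr7 (-0.82), Pfkp (-0.89), Fzd6 (-0.11), Cnga1 (-0.14), Rom1 (-0.37), Pde6a (-0.19), Pmel (-0.40), Cox6c (-0.30) and Ndufb5 (-0.75). Between P52 and P8 crystallins near 0 reversed: Cryba4 at -0.040 and -0.043 (both 75th percentile forms), -0.036 (no scaling) and -0.31 (cyclic loess), and Cryba1 at -0.22 (cyclic loess) and -0.030 (probe means). Under both percentile forms, no scaling, cyclic loess and the authors' values in either table, Crygd was at -0.087, -0.090, -0.083, -0.36 and -0.043, and Crybb3 at -0.098, -0.10, -0.095, -0.37 and -0.054. Crybb3 was at -0.65 with probe means (adjusted p = 0.00709, and 0.382 to 1 in its other reversals under these settings). Without single arrays Cryba2 ran from -0.18 to 0.044, Cryge from -0.25 to 0.37, Crygs from -0.29 to 0.21, Crybb3 from -0.10 to 0.13 and Crygd from -0.064 to 0.065. The cause was not tested.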

Other observations

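The genes named here were chosen after their values were seen, and the acinar list was added then. Genes best known from the exocrine pancreas were measured in lens. Of 8 tested acinar genes, 3 rose and 2 fell in lens against whole body (camera p = 0.0988, and p = 0.139 with an estimated correlation). Cela1, an elastase gene, was at 11.65 ± 0.12 (SD, n = 2) at P8 and 11.82 ± 0.12 at P52, against 4.65 in whole body, a difference of 7.03 ± 0.07 (SE). Amy2a5 was undetected at P8 (4.67 ± 0.11, against 4.72 in whole body) and at 8.79 ± 0.23 at P52. Gp2, undetected in whole body, was at 5.42 ± 0.07 at P8 and 9.54 ± 0.04 at P52. Only Gp2 and Amy2a5 of the list were called between P52 and P8.

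Of 4 tested Y-linked genes, only Ddx3y was called from P20 to P42. Uty was at 4.51, Eif2s3y at 5.17 and Kdm5d at 4.71 at P42, near the floor of the scale. Of 4 tested X-linked escape genes, 2 fell in that step.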
